A study of Mus musculus
Rattus norvegicus and Rattus norvegicus with 3 samples.

How the data were processed

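Hearts of 2 complemented chimeras (processed singly) and 3 pooled rat embryos were microdissected and dissociated with trypsin, per the labels' protocols, and single-cell RNA libraries were sequenced. The submitters' processing notes name Cell Ranger 7.0.0, Seurat 4.2.0 and the builds GRCm39 and mRatBN7.2. The deposited matrices hold UMI counts per gene and barcode, as whole numbers with no normalization, after Cell Ranger's calling of cells per the file names. The deposited feature lists show that the chimera libraries were counted on 32430 mouse and 25627 rat genes together, and the rat heart on the 25627 rat genes alone. Reads that match both species' genes can therefore be lost in the chimeras and kept in the rat heart. The authors also deposited UMI counts per barcode on each genome with a species call of rat, mouse or multiplet. Their annotation table of integrated rat cells gives labels of cell type, the percent of mitochondrial UMIs and scores of cell cycle and doublets per cell, made by the authors. All annotated cells were called singlets there, had at least 502 genes and under 10% mitochondrial UMIs (at most 9.97%), so the authors' doublet calls were used for rat cells. Other filters are not given in the sources used here, and 9 columns of that table were not used. Gene symbols were taken from the feature lists, without coordinates.

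Chimera 1, chimera 2 and the rat heart held 9215, 11195 and 10276 barcodes. Median genes per annotated cell were 3075, 3024 and 3760.5. A further 1930, 3639 and 3038 rat-called barcodes carried no annotation and were left out. Rat cells took the authors' labels. Mouse cells had no annotation, so the 2639 mouse-called barcodes of chimera 1 were filtered to at least 1000 genes and under 20% mitochondrial UMIs, which left 2080. They were clustered with scanpy 1.11.5 (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1) into 17 clusters, and Scrublet called 22 doublets (1.06%), which were kept. Clusters were named from markers fixed in advance, counted when in at least 25% of cells and at least 2-fold over the rest. A name needed at least 3 such markers, more than any other class, and no other class with more markers among the 10 leading genes. Those thresholds were set after the data were seen, and they left 7 clusters with 597 cells (28.7%) unnamed. Red blood cells numbered 550, neural cells 362, neural crest cells 295, second heart field or pharyngeal mesoderm 154, epithelium 83 and endothelium 39. The marker rule for cardiomyocytes asked for at least 3 of 6 fixed markers with 3 or more UMIs each.

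For expression, UMI counts of rat genes were summed over the cells of a label in each library, for labels with at least 30 cells per library, which left out macrophages. Sums were tested with edgeR 4.0.16 (TMM, filterByExpr, glmQLFit and glmQLFTest in R 4.3.3), chimeras against rat heart, with Benjamini-Hochberg adjustment at 0.05. The test has 1 residual degree of freedom and assumes that the rat heart library varies like the chimeras. All genes had a median log2 change of 0.04 in cardiomyocytes with TMM and 0.12 with total counts only. CPM of the tested sums are UMIs of a gene scaled to the total UMIs of tested rat genes after TMM. The ratios of rat heart to chimera for Igf2 and Grb10, and all CPM of mouse cells and of rat cells set beside them by class or as cells labelled Other, use plain UMI totals. The difference between endocardium and cardiomyocytes was tested as an interaction. The 27 gene lists were tested with camera (preset correlation 0.01, and estimated) and fry of limma 3.58.1, for lists with at least 3 members. Random lists (10000) were matched on expression in 10 bins. Rat and mouse cells were compared on log2(CPM + 1) over 16149 symbols found once in each species. List members and random genes needed a mean of at least 10 CPM over the rat and mouse cells of chimera 1. Groups with 0 counts were set at a floor of 3 counts, and intervals are exact 95% ones from scipy 1.17.1. Other tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, igraph 0.11.9, matplotlib 3.10.9 and DESeq2 1.42.0.

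Genes were named by a rule written before the data were examined, as were the lists, tests and most alternatives. In cardiomyocytes it takes the 10 highest and 10 lowest called changes, and 5 and 5 elsewhere. Such genes have a mean of at least 50 CPM, one direction in both chimeras, a symbol that is not an identifier, and under 5% of the pair's UMIs on the mouse copy. RGD placeholder symbols were treated as identifiers. Up to 4 members per list with at least 10 CPM and a fixed set of cardiac, endothelial and epicardial genes were added. Alternatives were DESeq2, its size factors in edgeR, total counts only, no low-count filter, equal cells per library, cells with at least 95% own-species UMIs, genes with 5% or more on the mouse copy left out, and each chimera left out. Shares were recomputed with own species calls at 90% and 95% of UMIs, with at least 2000 genes per cell, and without blood cells. Equal cells of each cardiomyocyte label were added after seeing the data. On simulated counts in which 200 genes of the cardiomyocyte comparison were changed, 7.46% of 1.5-fold, 62.7% of 2-fold and 90.9% of 4-fold changes were recovered over 13147 genes, and 4.46% of calls were false. For endocardium with 9063 genes these were 2.99%, 13.4% and 84.8%, with 4.29% false. All simulated libraries shared the same mean profile and dispersion. These rates therefore do not cover false calls from differences between libraries or between the references they were counted on.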

Results

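The series profiled single cells from the heart region of rat-mouse chimeras and from a rat heart region of matched stage. The chimeras are mouse embryos whose heart was complemented by rat cells. Chimera 1 and chimera 2 were single embryos at E10.5, each with its own library, and 3 rat embryos at E11.5 were pooled into 1 library. Chimera 1 held 9215 barcodes and 95211262 UMIs, chimera 2 held 11195 barcodes and 120892816 UMIs, and the rat heart held 10276 barcodes and 148992521 UMIs. The authors' annotation covered 4189, 7508 and 7238 rat cells in chimera 1, chimera 2 and the rat heart, with median rat UMIs of 9451, 9223.5 and 12434 per cell. Mouse genes took 1.41% of the UMIs in annotated rat cells of chimera 1 and 0.488% in those of chimera 2. Shares and counts of 1 library are given with 95% exact intervals, which cover counting error only.

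The first comparison asked which cells of the chimeric heart region were rat and which were mouse. The 2 chimeras differed widely. In chimera 1, 6119 of 8758 species-called barcodes were rat (69.9%, 95% interval 68.9 to 70.8), and 2639 were mouse. In chimera 2, 11147 of 11153 were rat (99.9%, interval 99.88 to 99.98), and 6 were mouse. Within chimera 1 the rat share depended on the cell class. All 596 named cardiomyocytes were rat, but no mouse cluster was given that name, and 12 mouse cells met a rule based on cardiomyocyte markers. Rat cells made up 304 of the endothelial and endocardial cells beside 39 mouse cells (88.6%, interval 84.8 to 91.8). Rat epithelial cells numbered 301 beside 83 mouse cells (78.4%, interval 73.9 to 82.4), and rat red blood cells 476 beside 550 mouse cells (46.4%, interval 43.3 to 49.5). Rat cells were those with the authors' labels, whereas mouse cells passed other filters and a naming rule that left 28.7% unnamed. The intervals do not cover this unlike selection. The mouse epithelial cluster was led by Afp and also had 3 hepatoblast markers among its leading genes. Rat hepatocytes carry a label of their own, so the epithelial share may set unlike classes side by side. In chimera 2 none of these classes held a named mouse cell, because mouse barcodes were too few to cluster.

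The count of 0 mouse cardiomyocytes depended on how cells were named. A mouse cluster of 48 cells in chimera 1 had 7 cardiomyocyte markers among its 10 leading genes and stayed unnamed. When barcodes of either species were classed by cardiomyocyte markers alone, 12 mouse cells stood beside 815 rat cells in chimera 1 (98.5% rat, interval 97.5 to 99.2), and 0 beside 1357 in chimera 2. Of the 12 mouse cells, 6 held UMIs of Myh6, the atrial and embryonic myosin heavy chain, together with Ttn and Gata4. Another 3 held UMIs of Myog or Mylpf, genes of skeletal muscle, and the remaining 3 held neither. Nkx2-5, a transcription factor of early cardiac progenitors, reached 14.0 CPM (interval 0.353 to 77.8) over the 6 Myh6-positive mouse cells. It reached 235 CPM (interval 224 to 247) over the 596 rat cardiomyocytes. The share of cells with an Nkx2-5 UMI was 16.7% in the former (1 of 6 cells, interval 0.421 to 64.1) and 77.9% in the latter (interval 74.3 to 81.1), at median depths of 12227.5 and 9843.5 UMIs, against 0.420% of rat erythrocytes at 21357.5 UMIs.

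**Figure D1:**
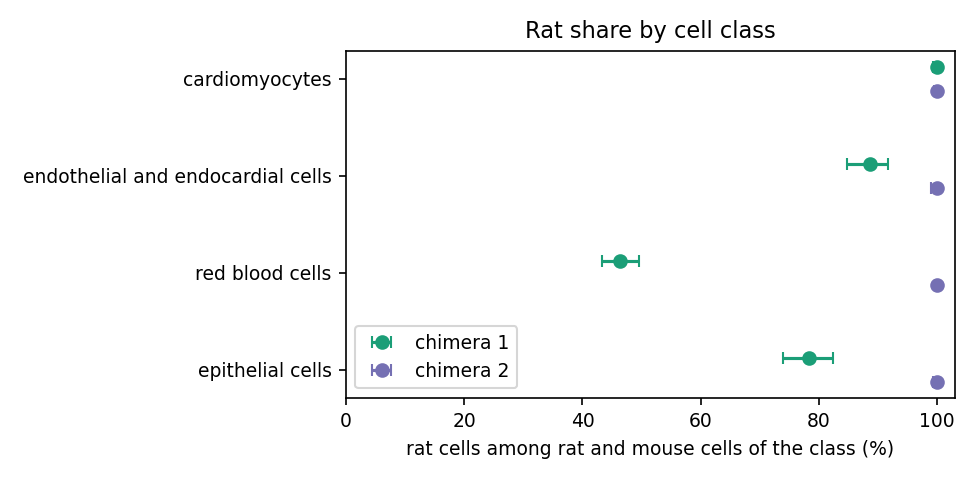
Rat cells as a percentage of rat and mouse cells of each class in chimera 1 and chimera 2, with exact 95% intervals for counting error. Cardiomyocytes stand at 100% by cluster names, against 98.5% in chimera 1 by the marker rule, and red blood cells of chimera 1 at 46.4%.

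Among annotated rat cells, the chimeras held fewer endocardial cells and more erythrocytes and macrophages than the rat heart. Endocardium made up 1.72% of rat cells in chimera 1 (interval 1.35 to 2.16), 0.972% in chimera 2 (0.763 to 1.22) and 5.62% in the rat heart (5.10 to 6.18). Erythrocytes made up 11.4%, 13.7% and 4.85%, and macrophages 1.53%, 1.35% and 0.263%. With at least 2000 genes per cell the erythrocyte shares were 9.30%, 6.88% and 4.90%. Ectoderm was also more frequent in the chimeras, with 3.51% and 2.12% against 0.718%. Hepatocytes differed between the chimeras, with 112 of 4189 cells (2.67%) and 30 of 7508 (0.400%), against 304 of 7238 in the rat heart (2.28%, 0.337% and 2.48% with at least 2000 genes per cell). Epithelial cells made up 7.19%, 7.73% and 10.8%. Cardiomyocytes made up 14.2% in chimera 1 (13.2 to 15.3), 10.4% in chimera 2 (9.73 to 11.1) and 13.4% in the rat heart (12.7 to 14.3), so the rat heart lay between the chimeras. Of the cardiomyocyte labels, ventricular cells made up 4.39%, 3.13% and 4.59%, atrial cells 3.53%, 2.52% and 2.51%, and atrioventricular canal cells 2.75%, 1.89% and 1.45%. Outflow tract cells made up 1.55%, 1.39% and 2.39%, and sinoatrial node cells 2.01%, 1.49% and 2.50% (1.86%, 1.30% and 1.57% with at least 2000 genes per cell). Epicardium stood at 4.46%, 4.45% and 4.71%. Venous endothelium made up 3.68%, 2.81% and 3.48%, arterial endothelium 1.86%, 1.08% and 0.939%, and cells labelled Other 47.8%, 55.0% and 51.0%. With 2 libraries against 1 no test was run, and the dissection of the region can set these shares.

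**Figure D2:**
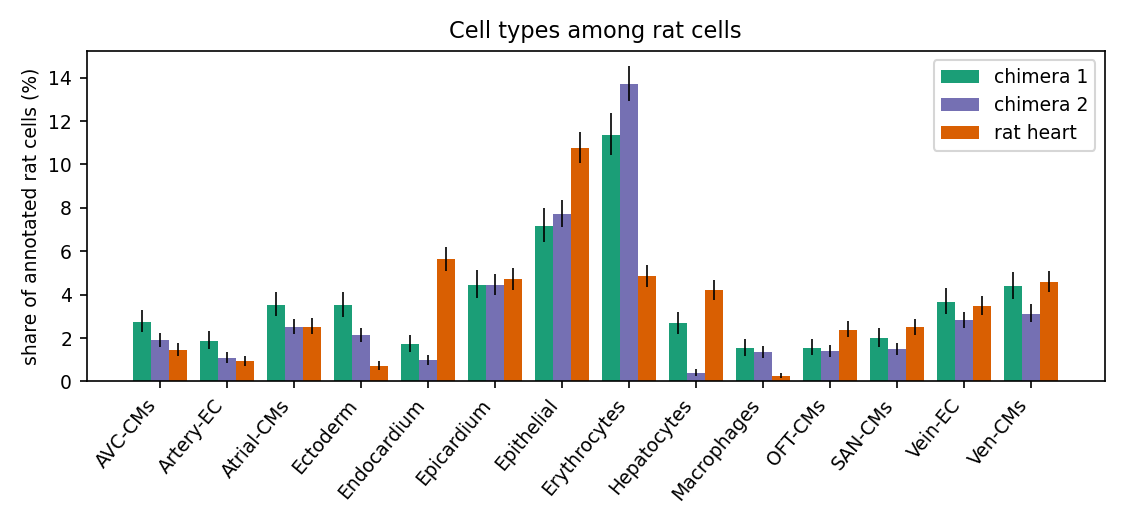
Share of annotated rat cells (%) with each label except Other in the 3 libraries, with exact 95% intervals for counting error. Endocardium is lower in both chimeras (1.72% and 0.972%) than in the rat heart (5.62%), and erythrocytes are higher.

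The main expression comparison asked how rat cardiomyocytes in the chimeras differed from those of the rat heart. Most measured genes of the hypoxia response and several of the integrated stress response were higher in both chimeras. Trib3, a pseudokinase induced by amino acid and endoplasmic reticulum stress, rose by a log2 change of 5.52 (SE 0.28, adjusted p = 1.4e-17). Slc2a3, a glucose transporter, rose by 4.65 (SE 0.25, adjusted p = 6.2e-17). Eno2 rose by 3.60, the collagen hydroxylase P4ha2 by 3.59 and the mTOR inhibitor Ddit4 by 3.58. Cadm2 rose by 3.38, the glycogen phosphorylase Pygl by 3.29, Igfbp2 by 3.17, Cox4i2 by 3.09 and the stress transcription factor Ddit3 by 3.02. Among 13147 genes tested, edgeR's quasi-likelihood test called 1462 higher and 1435 lower, and 2894 of the 2897 moved in the same direction in both chimeras. Both chimeras were set against the same rat heart library, and a call favours genes on which they agree. That count is therefore no separate check of the calls. At least 2-fold changes numbered 753 higher and 378 lower. The higher genes made up 50.5% of the calls with TMM scaling and 62.8% with total counts only. The test had 1 residual degree of freedom and assumed that the lone rat heart library varies like the chimeras, and DESeq2 called 485 genes higher and 439 lower. Total counts only gave 920 lower, and equal cells of each cardiomyocyte label gave 930 higher and 899 lower.

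Of 16 measured hypoxia response genes, 15 rose in cardiomyocytes and 0 fell, with a median log2 change of 2.29 (camera adjusted p = 2.9e-43; adjusted p = 0.933 with an estimated correlation). All 16 were higher when adjusted over the list alone. Ankrd37 rose by 3.80 and Higd1a by 0.82, while Ldha, lactate dehydrogenase A, stood at 0.38 (adjusted p = 0.145). Of 18 glycolysis genes, 7 rose and 0 fell, and 12 were higher when adjusted over the list alone (median 0.54, camera adjusted p = 5.1e-07; adjusted p = 0.933 with an estimated correlation). Hexokinase Hk2 rose by 1.83, while Gapdh at 0.16 and Pgam1 at 0.17 did not pass the test. Of 18 genes of the unfolded protein and integrated stress response, 10 rose and 3 fell, also when adjusted over the list alone (median 1.13, camera adjusted p = 4.5e-13; adjusted p = 0.933 with an estimated correlation). The members moved apart. Chac1, a target of the integrated stress response, rose by 5.86, whereas the endoplasmic reticulum chaperone Hspa5 fell by 0.91 and its cofactor Sdf2l1 fell by 0.88.

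Of 28 S phase genes, 0 rose and 14 fell, and 17 were lower when adjusted over the list alone (median -0.55, camera adjusted p = 1.3e-06; adjusted p = 0.933 with an estimated correlation). Ccne1, cyclin E1, fell by 1.82 and Rrm2, a subunit of ribonucleotide reductase, fell by 1.04, while Pola1 at 0.07 and Hells at -0.05 did not pass the test. Of 27 genes of G2 and M phase, 0 rose and 3 fell, with 2 lower when adjusted over the list alone, and the list was not called (camera adjusted p = 0.326). Cdc20 fell by 0.92 and Aurka fell by 0.65, and Mki67, a marker of cycling cells, stood at 0.11 (SE 0.19, adjusted p = 0.713). Markers of other origins moved as well. Of 4 sex-linked transcripts, 3 rose, also when adjusted over the list alone (median 1.52, camera adjusted p = 2.2e-04; adjusted p = 0.933 with an estimated correlation). These were the Y-linked Uty at 2.03, Eif2s3y at 1.53 and Kdm5d at 1.51. Of 15 cell types tested, Uty and Eif2s3y were higher in 14 and Kdm5d in 15. Whether the libraries differ in the sex of their rat cells was not tested. Of 9 red cell transcripts, 5 rose, also when adjusted over the list alone (median 1.40, camera adjusted p = 0.0015; adjusted p = 0.933 with an estimated correlation), with Hbg1 at 1.69, Hba-a2 at 1.62, Hbe1 at 1.40 and Hbz at 1.34. In erythrocytes themselves these transcripts changed less, with Hbg1 at 0.14, Hba-a2 at 0.49, Hbe1 at 0.04 and Hbz at -0.01. Whether red cell RNA in the suspension raised them in cardiomyocytes was not tested. The hypoxia, glycolysis, stress response, S phase, sex-linked and red cell lists were the 6 called among 27. None was called with an estimated correlation or by fry, a test of movement in one direction. With 1 residual degree of freedom both tests had little power, here and in the other cell types. Their outcome does not decide whether the lists moved.

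Most contractile and cardiac identity genes did not differ detectably. Cardiac troponin T Tnnt2 was at 7052 CPM in chimera 1, 7215 CPM in chimera 2 and 8686 CPM in the rat heart (log2 change -0.28, SE 0.18, adjusted p = 0.263). Nkx2-5 stood at a log2 change of -0.21 (adjusted p = 0.463), the atrial light chain Myl7 at -0.16 (0.556), Myh6 at 0.40 (0.150), Myh7 at 0.27 (0.376) and the ventricular light chain Myl2 at -0.48 (0.0571). Nppa, the atrial natriuretic peptide expressed in embryonic trabecular and atrial myocardium, rose by 1.23 (SE 0.21, adjusted p = 4.9e-05) over all cardiomyocytes. By label it rose by 2.02 in atrioventricular canal cells and fell by 1.87 in outflow tract cells. Of 23 contractile genes, 1 rose and 4 fell, also when adjusted over the list alone (median -0.14, camera adjusted p = 0.465). Acta1 rose by 0.52, while the adult-type troponin I Tnni3 fell by 0.77 and Cryab fell by 0.59. Of 10 trabecular genes, 2 rose and 3 fell, with 3 and 3 when adjusted over the list alone (camera adjusted p = 0.903). Nppb rose by 1.45, with a log2 ratio to the rat heart of 2.03 in chimera 1 and 0.48 in chimera 2, but fell by 1.99 in outflow tract cells. The conduction connexin Gja5 fell by 2.37 and Cited1 fell by 1.04. Of 18 cardiac transcription factors, 0 rose and 2 fell, with 1 lower when adjusted over the list alone (camera adjusted p = 0.406). Irx4 fell by 0.56. Of 22 calcium handling and excitation genes, 3 rose and 5 fell, with 3 and 6 when adjusted over the list alone (camera adjusted p = 0.748). Asph rose by 1.69 and Kcnj3 by 1.27, while Cacna1d fell by 0.95.

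**Figure D3:**
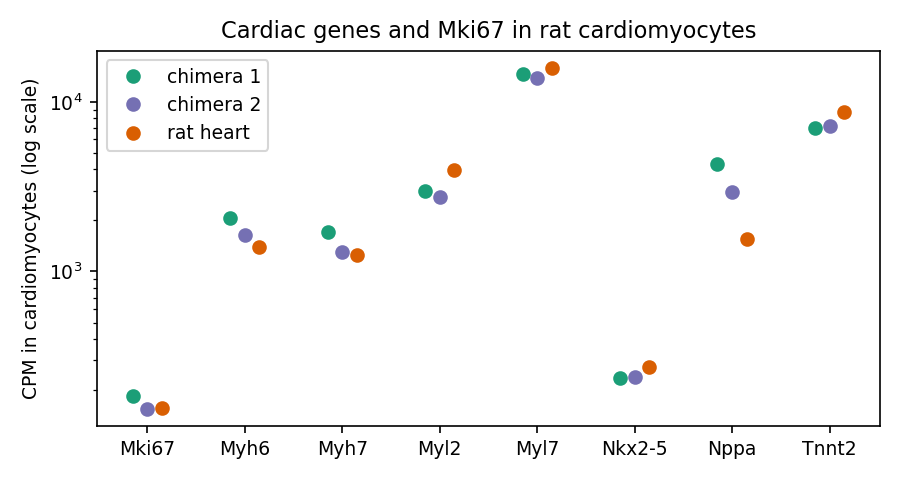
CPM (log scale) of cardiac genes and Mki67 in rat cardiomyocytes of chimera 1, chimera 2 and the rat heart, 1 point per library. Nppa differs most, with 4311 and 2931 CPM in the chimeras and 1548 CPM in the rat heart.

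The regional lists were not called in cardiomyocytes. Of 11 ventricular genes 0 rose and 1 fell (2 and 2 when adjusted over the list alone; camera adjusted p = 0.748), and of 13 atrial genes 1 rose and 1 fell (1 and 1; 0.903). Of 13 atrioventricular canal and pacemaker genes 1 rose and 1 fell (1 and 0; 0.903), with Cacna1h at 0.68 and Isl1 at -0.61. Of 13 outflow tract genes 1 rose and 2 fell (1 and 2; 0.777), with Nrp2 at -0.77. Metabolic lists other than glycolysis were also not called. Of 31 oxidative phosphorylation genes 1 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.709), where cytochrome c Cycs fell by 1.03 and Atp5mc1 fell by 0.72. Of 18 fatty acid oxidation genes 1 rose and 0 fell (0.776), and of 17 cholesterol synthesis genes 0 rose and 2 fell (0.725), with the same counts when adjusted over the list alone. Immediate early and heat shock genes went both ways, with 6 of 19 higher and 5 lower, or 7 and 5 when adjusted over the list alone (median 0.16, camera adjusted p = 0.465). Atf3 rose by 3.79 and Egr1 by 1.66, while Hsph1 fell by 1.32 and Hspa8 fell by 1.04. Of 19 p53 targets 4 rose and 2 fell (camera adjusted p = 0.847), of 8 pluripotency genes 2 rose and 3 fell (0.903), and of 23 matrix genes 5 rose and 2 fell (0.903), also when adjusted over the list alone. Of 29 signalling genes 4 rose and 0 fell, with 3 higher when adjusted over the list alone (0.748). None of 5 interferon genes passed either adjustment (0.688). Of 8 hepatic genes 1 rose and of 7 neural genes 1 fell (0.918 and 0.903), with 0 of each when adjusted over the list alone. The median and the camera direction had opposite signs for the trabecular (median 0.24), imprinted (0.15), pluripotency (0.18) and matrix (-0.05) lists, and none of these was called.

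Imprinted genes moved in both directions. Of 27 measured, 9 rose and 7 fell, or 10 and 7 when adjusted over the list alone (median 0.15, camera adjusted p = 0.406). Igf2, the fetal growth factor expressed from the paternal allele (ENSRNOG00000020369), held 18 UMIs in cardiomyocytes of chimera 1, 3 in chimera 2 and 14451 in the rat heart, or 2.72, 0.325 and 938 CPM (adjusted p = 6.6e-23). By plain UMI totals, without TMM, the rat heart level was 330.0 times that of chimera 1 (interval 209 to 557) and 2687 times that of chimera 2 (interval 919 to 13029). Grb10, a growth factor receptor adaptor (ENSRNOG00000004290), fell by 5.80 (SE 0.22, adjusted p = 3.7e-22), and rat cells held 213 UMIs of its mouse copy in chimera 1 and 0 in chimera 2. By the same totals the rat heart level of Grb10 was 45.1 times that of chimera 1 (interval 36.6 to 56.3) and 61.9 times that of chimera 2 (interval 50.2 to 77.3). Peg10 rose by 2.04, Sgce by 1.52 and H19, the noncoding neighbour of Igf2, by 1.13. Igf2 and Grb10 were lower in all 15 cell types tested, and H19 was higher in 13. In mouse cells of chimera 1, counted on the same joint reference, Igf2 was also low, at 0.388 to 16.0 CPM over the mouse classes, whereas Grb10 was at 248 to 901 CPM. The rat heart cell types held 167 to 1321 CPM of Igf2 and 110.5 to 817 CPM of Grb10 after TMM, whereas the mouse values use plain totals.

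**Figure D4:**
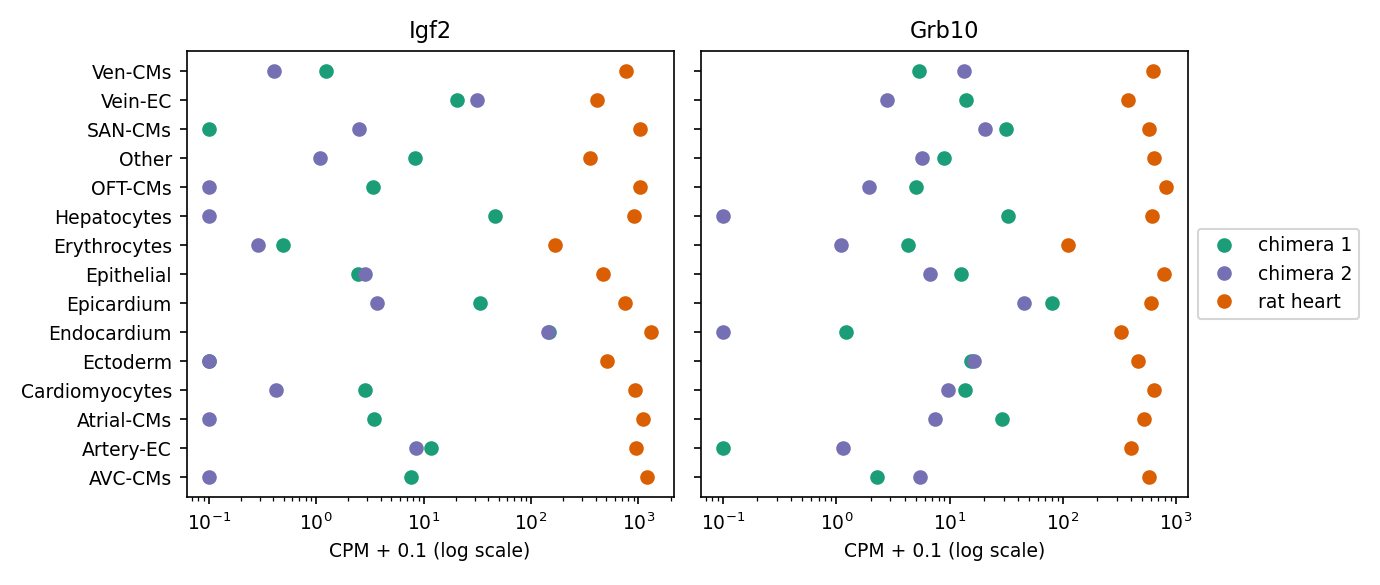
Igf2 and Grb10 (CPM + 0.1, log scale) in rat cells of each label in the 3 libraries, 1 point per library, where a point at the left edge is 0 UMIs. The rat heart lies above both chimeras in every label for both genes.

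Among genes with a symbol, a mean of at least 50 CPM and under 5% of UMIs on the mouse copy, the lowest changes in cardiomyocytes after Igf2 were Ddx5, which fell by 2.23, Arf1 by -2.06, the histone variant H2az1 by -1.96 and Eif4g2 by -1.96. Sod2 stood at -1.70, Mpc1 at -1.69, Ccng1 at -1.67, the troponin Tnni2 at -1.60 and Edf1 at -1.57, all past the test. Ddx5, Arf1, H2az1 and Eif4g2 were lower in all 15 cell types, with Ddx5 between -2.64 and -1.58. In mouse cells of chimera 1, Ddx5 was at 72.9 to 198 CPM, Arf1 at 35.9 to 126 CPM and Eif4g2 at 96.1 to 161 CPM, where red blood cells held the lowest values. Rat cells labelled Other held 176, 113 and 145 CPM in chimera 1 and 697, 363 and 532 CPM in the rat heart. H2az1 was at 867 to 1597 CPM in mouse cells, above the 568 CPM and 385 CPM of rat cells labelled Other in the chimeras, with 1885 CPM in the rat heart. The chimera libraries were counted on both species' genes and the rat heart on rat genes alone. Reads that match both species can therefore be lost in the chimeras only. Such a loss could also lower genes of S phase, oxidative phosphorylation and heat shock, and was not tested there.

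In endocardium, the inner lining of the heart, most measured hypoxia and glycolysis genes were also higher in both chimeras. Eno2 rose by 6.33 (SE 0.48, adjusted p = 1.7e-35), Depp1 by 6.27, Pygl by 5.25, Slc2a3 by 4.41 and the matricellular Ccn2 by 4.30. Igf2 fell by 3.19, Cpa1 fell by 3.15, the caveolar protein Cavin2 fell by 2.71, Col23a1 fell by 2.14 and H2az1 fell by 2.09. The VEGF receptor Kdr rose by 1.13 (adjusted p = 0.00999), while Pecam1 at 0.32 (0.637) and Cdh5 at 0.30 (0.665) did not pass. Of 9063 genes tested, 347 rose and 322 fell. Hypoxia response genes rose in 15 of 16 (16 when adjusted over the list alone; median 3.23, camera adjusted p = 8.2e-60), with Ndrg1 at 5.32 and Bnip3 at 4.13. Glycolysis genes rose in 11 of 15 (12 when adjusted over the list alone; median 1.23, 2.5e-19), with Slc16a3, a lactate exporter, at 3.83. Immediate early genes rose in 6 of 18 and fell in 1 (7 and 2 when adjusted over the list alone; median 0.68, 2.3e-05), with Egr1 at 2.99 and Zfp36 at 2.59. Signalling genes rose in 6 of 22 (8 higher and 1 lower when adjusted over the list alone; 0.0016). S phase genes fell in 9 of 29 (10 when adjusted over the list alone; 7.1e-07), oxidative phosphorylation genes in 2 of 28 (2; 0.0057) and G2 and M phase genes in 2 of 27 (2; 0.030). All 3 sex-linked transcripts (3; 2.1e-06) and 2 of 5 red cell transcripts (4; 0.0057) were higher. With an estimated correlation the adjusted p of these lists lay between 0.791 and 0.883, and none was called.

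Across the 14 labels tested beside all cardiomyocytes, the sums of calls were 10447 higher and 10436 lower (2977 and 2439 with DESeq2), from 168 genes in hepatocytes to 4166 in cells labelled Other. These labels share the same 3 libraries and include the cardiomyocyte subtypes, so they are not independent. The median of the hypoxia list ranged from 1.06 in erythrocytes, where 7 of 15 genes rose (9 when adjusted over the list alone), to 3.23 in endocardium, and the list was called in all 15 fits (adjusted p between 0.691 and 0.984 with an estimated correlation). Glycolysis was called higher in 14 of the 14 labels, red cell and sex-linked transcripts in 13 each and the stress response in 11. S phase was called lower in 12 labels and higher in 1, oxidative phosphorylation lower in 10, and contractile and G2 and M phase genes lower in 6 each. With an estimated correlation none of these lists was called in any label, with adjusted p of at least 0.691. Slc2a3, Eno2, P4ha2, Ddit4, Cadm2 and Cox4i2 rose in all 15 fits. In epicardium G0s2 rose by 4.26 and Eno2 by 3.91, while Pnmt fell by 2.96, and Wt1, an epicardial transcription factor, stood at 0.19 (adjusted p = 0.563).

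**Figure D5:**
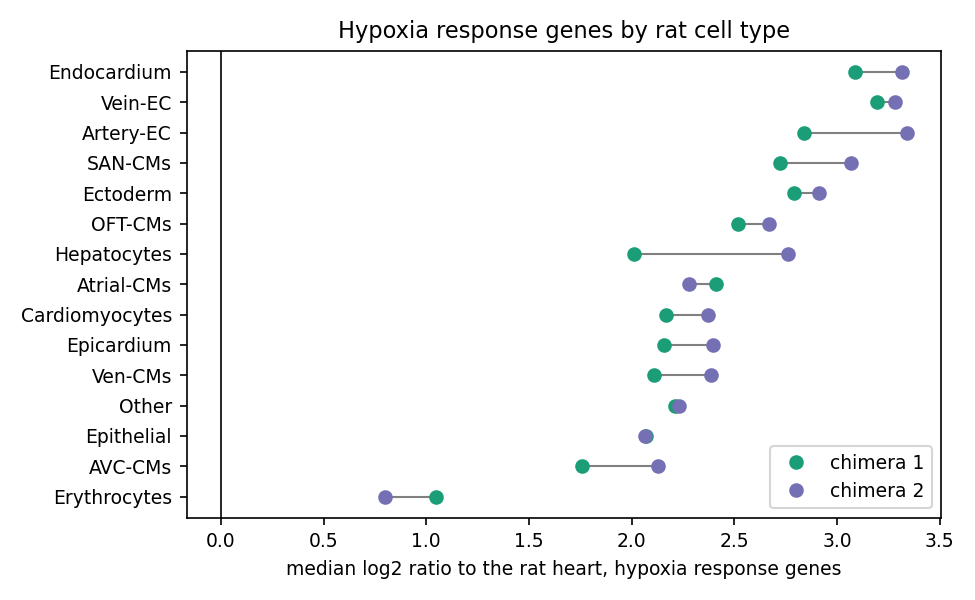
Median log2 ratio to the rat heart of the hypoxia response genes in rat cells of each label, with 1 point per chimera and a line joining them. All medians lie above 0, with fitted medians from 1.06 in erythrocytes to 3.23 in endocardium.

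Rat and mouse cells of the same class could be set side by side in chimera 1 alone, so this comparison has no replicate check and no test. In endothelial and endocardial cells, hypoxia response genes had a median log2 ratio of rat to mouse of 0.14 over 16 genes, at percentile 79.4 of 10000 random lists of matched expression. Members differed, with P4ha1 at 804 CPM in rat and 351 CPM in mouse cells. The mouse cells lay above the rat heart in all 16 genes (median log2 ratio 3.09, against 0.047 for random lists). In red blood cells the mouse cells lay above the rat heart in 14 of 14 (median 1.36, against 0.363 for random lists, percentile 99.87). There the median log2 ratio of rat to mouse was -0.68 (percentile 32.3). Genes were kept by their level in chimera 1 alone, so members high only in the rat heart could not enter these counts. The random lists passed the same filter. The largest gaps towards mouse in endothelial cells were Abca1 at -5.41, Nrxn3 at -5.35, Trpm3 at -4.91, Sntb1 at -4.49 and Fgfr2 at -4.40. In red blood cells they were Ptp4a3, St3gal6, Vangl1, Rragd and Sgk3, with 2 to 7 UMIs in rat cells and 518 to 1160 in mouse cells. The largest gaps towards rat were genes such as Ikzf4, Colec11, Vps25, Zc3h10 and Man2b2, with 0 to 5 UMIs in mouse endothelial cells and similar levels in the rat heart. These ratios hold differences between the annotations of the 2 genomes as well as between cells.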

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

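The tests of explanations in this part were all chosen after the results were seen; the test of the difference between cell types was run on every gene.

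The change between chimeras and rat heart differed between endocardium and cardiomyocytes for 294 of 13542 genes by the interaction test, 179 with a larger log2 change in endocardium and 115 with a smaller one. The fit had 1 residual degree of freedom. Values are endocardium minus cardiomyocyte log2 changes. Igf2 stood out at 6.21 (SE 0.31), since endocardial cells kept more of it than cardiomyocytes. Among called genes linked to low oxygen and glucose use, the difference was 5.37 for Depp1, 3.02 for Slc16a3, 2.65 for Eno2, 1.98 for Bnip3, 1.97 for Pygl and 0.72 for Ldha, all larger in endocardium, and -1.61 for Cox4i2. In endocardium Depp1 was at 242 CPM in chimera 1 and 49.6 CPM in chimera 2. Depp1 and Eno2 were both low in endocardium of the rat heart, at 1.88 CPM each. Of the fixed hypoxia list, Slc2a1, Bnip3, Ldha, Vegfa and Adm were called. Pdk1, Egln3, Ero1a, P4ha1, P4ha2, Ndrg1, Egln1, Kdm3a, Higd1a, Ankrd37 and Mxi1 were not, and the list as a whole was not tested for this difference. Called genes linked to stress had -2.98 for Chac1, -1.99 for Ddit3, -1.84 for Sesn2, -1.63 for Mthfd2 and -1.37 for Ddit4, but 0.83 for Hspa5. The stress response list as a whole was not tested for this difference. Immediate early genes had 1.91 for Zfp36, 1.39 for Btg2, 1.30 for Egr1 and 0.98 for Klf2, but -1.84 for Atf3. That list was not tested as a whole for this difference either. The p53 target Plk2 had -1.12. Matrix and contractile genes had 2.37 for Ccn2, 2.14 for Col1a1, 1.34 for Tpm1, 0.99 for Lamb1, 0.70 for Sparc, -1.22 for Col3a1 and -3.33 for Col23a1. Of the other genes, signalling, regulatory and channel genes had 2.67 for Bmp2, 1.97 for Mpped2, 1.87 for Nrp2, 1.56 for Cacna1c, 1.51 for Hey1, 1.25 for Meis1, 1.02 for Lbh, 0.88 for Gata6, -1.13 for Nrg1 and -1.94 for Hand2, which had 2 UMIs in endocardium of chimera 2. Grb10 had -3.34, with 1 and 0 UMIs in endocardium of the chimeras.

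Igf2 was lower in every rat cell type of the chimeras. A loss of reads on the joint reference of one size in every type is argued against by the endocardial difference of 6.21. A loss that hits both species and varies between types stays open. By plain totals, Igf2 of mouse cells in chimera 1 reached at most 16.0 CPM in any class, below the lowest rat heart type at 167 CPM after TMM. The same loss is argued against for Grb10, where mouse cells reached 901 CPM. A change across imprinted genes of the donor cells is a hypothesis and does not rule out the counting loss for Igf2. Of 27 imprinted genes 16 were called in cardiomyocytes, at percentile 99.99 of random lists with a median of 7. That count takes both directions together and includes Igf2 and Grb10, so it is not independent of the falls to be explained.

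Chimera 2 held hardly any mouse cells, with 6 mouse-called barcodes, of which 3 had over 4000 mouse UMIs and 0 shared a barcode with chimera 1. Its cardiomyocytes differed from those of the deposited rat heart in the hypoxia list, with a median log2 ratio of 2.37. That value cannot exclude a rat heart carrying the wrong label, because embryo handling could raise the list in any heart. Mouse blood present but not called as cells is argued against by mouse globin at 8.57 CPM in annotated rat cells, against 1407 CPM in chimera 1. A high rat contribution or the part dissected could each account for it and were not tested.

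Data outside the comparisons also held cardiomyocyte signal. Rat-called barcodes without annotation that met the cardiomyocyte marker rule numbered 199 in chimera 1, 522 in chimera 2 and 710 in the rat heart.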

How the results depend on the processing

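No paired analysis was possible because chimera 2 held 6 mouse barcodes, so the planned test of rat against mouse cells in both chimeras, with and without the embryo as a block, was not run. In cardiomyocytes DESeq2 called 485 genes higher and 439 lower, all 924 among the 2897, and over the 14 other labels 2977 higher and 2439 lower. Total counts only gave 920 lower in cardiomyocytes, and equal cells of each cardiomyocyte label, added after seeing the data, gave 930 higher and 899 lower. Of 6 called lists, 0 were called with an estimated correlation and 0 by fry, which had little power with 1 residual degree of freedom. For these changes the cause was not tested. The rat share of cardiomyocytes in chimera 1 was 98.5% by the marker rule. Hba-a2 in endocardium changed sign to -0.020 with equal cells per library. Without blood cells, a smaller denominator raised shares in chimera 1 to 16.3% for cardiomyocytes, 8.33% for all endothelial labels, 8.25% for epithelial cells and 54.9% for Other. In chimera 2 they rose to 12.3% for cardiomyocytes, 5.72% for endothelial labels, 2.23% for atrioventricular canal, 2.96% for atrial and 3.69% for ventricular cells, 2.49% for ectoderm, 5.24% for epicardium, 9.10% for epithelial cells, 3.31% for venous endothelium and 64.7% for Other, and in the rat heart Other stood at 53.8%. With at least 2000 genes per cell, chimera 1 held 9.30% erythrocytes and 49.4% Other, and chimera 2 held 11.3% cardiomyocytes, 3.57% ventricular cells, 8.38% epithelial cells, 6.88% erythrocytes and 59.4% Other. The rat heart held 0.508% ectoderm, 2.48% hepatocytes, 1.57% sinoatrial node cells and 52.8% Other, since shallow cells were left out. Beyond these, 170 summary values and 3366 of the gene, list and label values kept their direction and side of the threshold or stayed within their spread, 201 lost the call or count, 19 gained it and 6 moved. Leaving out either chimera reversed no called gene among the 359 gene values, as ratios of 1 library to 1 with no test. In these tallies some of the 170 summary values could not change. The cut on own-species UMIs left out no annotated cell of chimera 2 or of the rat heart, so their shares stayed identical. Chimera 2 had no named mouse cell, so its rat share of each named class could not fall in any setting. These values are no check of the results. A gene called in neither setting was counted as unchanged whatever its sign. The leading genes were also chosen for one direction in both chimeras, so little reversal was possible. In simulated cardiomyocyte counts with 3 libraries, 7.46% of 1.5-fold changes were recovered.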

Other observations

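The tests of explanations in this part were all chosen after the results were seen, and the imprinted genes named next were chosen after their values were seen.

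Several imprinted genes differed between the chimeras in cardiomyocytes. Igf2r, the receptor that clears Igf2, was at 59.3 CPM in chimera 1, 536 in chimera 2 and 569 in the rat heart. Cdkn1c, a growth-restraining cell cycle inhibitor, was at 505 CPM, 1813 CPM and 3238 CPM, and Plagl1 at 332, 159 and 137 CPM. Each chimera is 1 library, so these differences between embryos were not tested.

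Hypoxia response genes were higher in rat cells of the chimeras. Reads lost to mouse genes of the joint reference are argued against, because such a loss lowers counts and the list median stayed at 2.38 with total counts only. A dissociation response of the immediate early kind stays open, because in cardiomyocytes those genes moved both ways with a median of 0.16. Among the 14 other labels, camera with the preset correlation called that list higher in 3, endocardium among them, and lower in 1. With an estimated correlation it was called in none. A state shared by all cells of a chimera library, rather than one of rat cells, stays open. In mouse endothelial cells of chimera 1 the list median over the rat heart was at percentile 100 of random lists. That ratio also holds differences between the species and their annotations, and the series has no mouse heart without rat cells. Embryo handling, the pooling of 3 rat embryos, the stage difference, the origin and sex of the rat cells and the host environment stay open. They cannot be separated by these 3 libraries.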
